A study of Rattus norvegicus with 60 samples.

How the data were processed

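Rat dorsal root ganglion libraries of 3 kinds were used, each with 10 control and 10 CFA libraries. Per the labels' protocols, mRNA libraries were made by poly-A selection with a NEBNext Ultra kit and small RNA libraries with a NEBNext multiplex kit. The submitters' processing notes name FastQC 0.11.8, cutadapt 2.1.0, STAR 2.7.0, DESeq2 1.29.0, Trim Galore 0.6.4 and Bismark 0.22.0 and the genome build rn4 for the whole series, without saying which step used which. The counting rule and the use of strand are not given in the sources used here, so genes that overlap or share reads with near copies are uncertain.

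Per the file headers, the deposited mRNA and small RNA files hold raw counts, per Ensembl gene (23918 identifiers) and per miRNA feature (439 hairpins and 879 mature arms). The deposited bisulfite files hold a fraction, the mean methylation level per region, and the number of CpGs, per the file headers. They give no read coverage, so the depth behind a methylation level is unknown. Coordinates are printed as the files list them, and whether starts are counted from 0 or 1 is not given in the sources used here. The labels describe the rats as 10 randomly chosen pairs but do not say that library numbers mark pairs, or that equal numbers in the 3 assays mark 1 rat.

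Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test with robust settings, TMM factors, filterByExpr), CFA against control, with Benjamini-Hochberg adjustment at 0.05 and no minimum fold. Log2 fold changes and differences are CFA minus control. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Groups of miRNAs were tested with camera from limma 3.58.1 on voom values, with a preset correlation of 0.01. Mature arms were the members, and each group needed at least 3 tested arms. Methylation levels were tested per region with limma (robust empirical Bayes) where at least 5 libraries per group had a value. Single values were compared by two-sided permutation tests with 100000 resamples. Other splits of the 20 libraries were drawn to a total of 100 per assay, the real one included.

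On simulated counts with a known 1.5-fold, 2-fold or 4-fold change, the mRNA test recovered 35 of 67, 59 of 67 and 66 of 66 changed genes, and the small RNA test 36 of 65, 54 of 66 and 65 of 65. Simulated genes varied independently, unlike these libraries. Simulated shifts in methylation of 0.1, 0.2 and 0.3 were recovered in 1, 8 and 33 of 60 regions. These values followed a normal distribution without the bounds of a fraction, with the same SD in every library of a region. Most simulated regions were left unshifted, whereas the real regions are a list selected for a difference. Recovery in the real regions may therefore differ.

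The lists, the rule for named features, the tests and most other settings were fixed before the data were examined. The rule took genes past the threshold and, where a direction had fewer than 5, the 5 with the smallest p. It took 3 members with the smallest p per miRNA group, and the 5 largest differences in each direction among regions with a value in every library. Named small RNAs ranked by p had a mean of at least 10 CPM, a minimum the rule set for called ones and that was applied to these as well. The 2 called regions are named although the rule does not reach them. The other settings fixed then were DESeq2 1.42.0, RLE and upper-quartile factors, no filter or a stricter one, the replicate number as a block, sample quality weights, surrogate variables from sva 3.50.0, an estimated correlation, fry, a logit scale with an offset of 0.01, regions complete in every library, and leaving out CFA 8, 9 and 10. Leaving out each library in turn, leaving out libraries that stood apart, testing arms or hairpins only, arms only with an estimated correlation, hairpins as group members and a miRNA covariate were chosen after seeing the data.

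The reference table used here paired 0 of 23918 Ensembl identifiers with a symbol. For that reason 32 named gene groups, the AP-1 subunits, the AP-1 motif in promoters and the genes near methylated regions, which were planned, were not analysed here. In the mRNA figures and text at most 2 identifiers of each direction are printed.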

Results

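Dorsal root ganglia, which hold the cell bodies of the sensory neurons that supply skin and muscle, were taken from rats given complete Freund's adjuvant (CFA) and from untreated rats. CFA is a suspension of killed mycobacteria in oil that sets off a lasting local inflammation, and it was injected under the skin of 1 foot in a volume of 0.1 mL. Poly-A mRNA, small RNA and bisulfite-converted DNA were each sequenced in 10 control and 10 CFA libraries. The mRNA libraries held between 15607906 and 21611397 counts, with a mean of 16669500 ± 1087470 in controls and 18535100 ± 1595060 in CFA (SD, n = 10 each; p = 0.00661, two-sided permutation test). The small RNA libraries held between 3360055 and 13097872 counts, with the most in CFA 9 (13097872) and CFA 10 (12799704). Of all pairs of libraries within a group, CFA 9 and CFA 10 had the most similar counts in both the mRNA and the small RNA set, by a chi-square comparison. Why these 2 are so alike was not tested, and leaving out single libraries does not remove both. On the second principal component of the small RNA libraries, CFA 8, 9 and 10 lay highest, at 16.1, 8.55 and 7.74. The next was control 3 at 4.07. The bisulfite libraries CFA 8, 9 and 10 stood apart as well, as described below. The series title names the transcription factor complex AP-1 as a candidate hub of inflammation-induced hyperalgesia. The labels give neither the time between injection and dissection nor the sex of the rats.

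The first comparison asked which mRNAs differed in the ganglia of injected rats. Of 15124 genes tested, 5 rose in CFA and 0 fell, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ENSRNOG00000006151 rose from 1.24 ± 0.787 CPM in controls to 15.0 ± 6.04 CPM in CFA (n = 10 each), a log2 fold change of 3.58 (SE 0.32, edgeR adjusted p = 1.54e-06). ENSRNOG00000006360 rose from 0.674 ± 0.294 to 4.16 ± 1.19 CPM, a log2 fold change of 2.62 (SE 0.23, edgeR adjusted p = 1.54e-06). The other 3 genes that rose were 3.94-fold, 2.11-fold and 6.74-fold higher in CFA. With the replicate number as a block, these 3 were not called (edgeR adjusted p = 0.0815, 0.0815 and 0.248), at log2 fold changes of 1.90, 1.07 and 2.88. The 2 genes named above were still called with the block. Whether replicate numbers mark pairs of rats is not stated in the labels. All 5 were genes of low abundance, with means between 0.905 and 8.10 CPM over the 20 libraries. For each of them, 10 of 10 CFA libraries lay above every control library, and no other tested gene separated the groups completely, which chance alone gives for 0.00108% of genes. The files pair no Ensembl identifier with a gene name, and neither did the reference table, so AP-1 subunits and the named gene groups were not analysed here in the mRNA libraries.

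**Figure D1:**
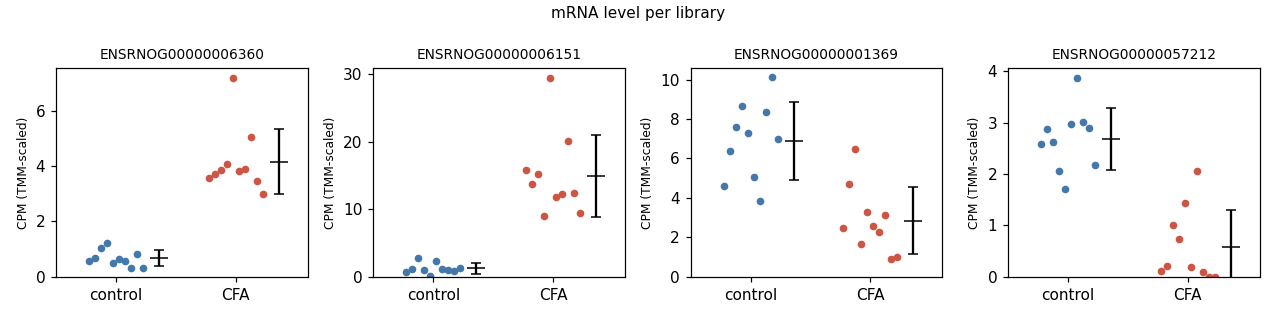
TMM-scaled CPM (vertical axes, linear, from 0) of 4 genes in 10 control (blue) and 10 CFA (red) mRNA libraries, 1 point per library, with the group mean and SD as a black bar. ENSRNOG00000006360 and ENSRNOG00000006151 lay higher in 10 of 10 CFA libraries than in every control library, while ENSRNOG00000001369 and ENSRNOG00000057212 did not pass the edgeR threshold.

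No gene was called lower by edgeR. The smallest p among genes with lower levels belonged to ENSRNOG00000001369, at 6.89 ± 1.96 CPM in controls and 2.84 ± 1.71 CPM in CFA, with 8 of 10 CFA libraries below every control library (log2 fold change -1.28, SE 0.29, edgeR adjusted p = 0.565). It passed the threshold with DESeq2 (adjusted p = 0.0162), sample quality weights (adjusted p = 0.00916) and surrogate variables (adjusted p = 0.0296), and with edgeR when CFA 3 was left out, which gave 6 calls. ENSRNOG00000057212 averaged 2.68 ± 0.603 CPM in controls and 0.586 ± 0.71 CPM in CFA, with 9 of 10 CFA libraries below every control library (log2 fold change -2.18, SE 0.52, edgeR adjusted p = 0.823). With sample quality weights it passed the threshold, at a log2 fold change of -3.23 (adjusted p = 0.0427). In all, 314 genes had an unadjusted p under 0.05, where 756.2 would be expected if no gene differed and genes varied independently. This count depended on the setting. It was 957 with sample quality weights, 900 with surrogate variables and 957 with the miRNA covariate. In the other settings it lay between 265 with the replicate block and 688 with no filter. The 95% interval of the log2 fold change lay within 2-fold in both directions for 95.4% of the genes tested. Libraries CFA 3, control 10, control 1 and control 3 stood apart in a principal component analysis, and the same 5 genes were called without them.

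The second comparison asked which small RNAs differed. Of 692 small RNA features tested, comprising 539 mature miRNA arms and 153 hairpin precursors, 0 passed the edgeR threshold. An unadjusted p under 0.05 was found for 163, where 34.6 would be expected if no feature differed and features varied independently. Among other splits of the 20 libraries, the highest such count was 171, so an excess of this size can arise without the CFA grouping. How many of the other splits reached 163 was not recorded, so how often it arises is unknown. DESeq2 called 32, of which 6 arms were higher, 2 arms were lower and 24 hairpins were lower. The smallest edgeR adjusted p of all was 0.0720. The number of features with a read averaged 1238.6 ± 45.5 in control and 1170.2 ± 69.0 in CFA libraries (p = 0.0128, two-sided permutation test). The values that follow are therefore those of features ranked by p, not of calls. A range in parentheses after a log2 fold change gives its lowest and highest value under the other settings run, single left-out libraries apart. For miR-384-3p, miR-125a-5p and let-7e-3p, among others, the lowest came from arms only without controls 1 to 3 and CFA 3, 8, 9 and 10. For other arms it came from upper-quartile factors or surrogate variables.

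Among arms with higher values in CFA, rno-miR-122-5p, an arm known for its abundance in liver, had the smallest p. It averaged 2.28 ± 0.555 CPM in controls and 77.3 ± 226 CPM in CFA (edgeR adjusted p = 0.0723), but CFA 8 alone stood at 719 CPM and the other 9 CFA libraries between 1.01 and 17.7 CPM. Its log2 fold change was 5.07, between 0.71 and 5.22 under the other settings that keep CFA 8, 1.40 without CFA 8, and 0.043 with arms only and without controls 1 to 3 and CFA 3, 8, 9 and 10. Without CFA 6 it passed the threshold (adjusted p = 0.0493). rno-miR-204-5p averaged 3876 ± 614 CPM in controls and 5591 ± 1598 CPM in CFA, with 6 of 10 CFA libraries above every control library (log2 fold change 0.53, SE 0.15, edgeR adjusted p = 0.102). rno-miR-384-3p averaged 270.3 ± 29.4 and 377 ± 94.2 CPM, with 8 of 10 CFA libraries above every control library. rno-miR-664-1-3p averaged 23.9 ± 5.0 and 35.3 ± 7.49 CPM, and rno-miR-191a-3p averaged 9.77 ± 0.979 and 13.1 ± 1.72 CPM. The log2 fold changes of miR-384-3p, miR-664-1-3p and miR-191a-3p were 0.48 (0.28 to 0.67), 0.56 (0.37 to 0.73) and 0.42 (0.26 to 0.60). DESeq2 called miR-204-5p, miR-384-3p, miR-664-1-3p and miR-191a-3p higher, with adjusted p-values of 0.0397, 0.0364, 0.0267 and 0.0364. Sample quality weights called miR-204-5p and miR-664-1-3p, both with an adjusted p of 0.0411. Without CFA 8, edgeR called miR-204-5p, miR-384-3p and miR-664-1-3p, each with an adjusted p of 0.0343, and without control 10 it called miR-664-1-3p (adjusted p = 0.0475).

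Among features with lower values in CFA, rno-miR-542-1-3p averaged 800.4 ± 236 CPM in controls and 518 ± 146 CPM in CFA (log2 fold change -0.63, SE 0.18, edgeR adjusted p = 0.102). rno-miR-881-3p averaged 38.5 ± 47.6 and 10.5 ± 7.46 CPM, with a log2 fold change of -1.87 (SE 0.58; -2.02 to -0.13) that was -0.35 without controls 1, 2 and 3. rno-miR-6323-5p had a log2 fold change of -1.27, and the hairpin rno-mir-192 one of -1.37; without controls 1, 2 and 3 these were -0.82 and -0.84, with surrogate variables -0.24 and -0.53, and with hairpins only rno-mir-192 was at -0.51. The hairpin rno-let-7e had a log2 fold change of -1.78, of -0.73 without control 5, which stood at 135 CPM, and of -0.38 with surrogate variables. DESeq2 called miR-542-1-3p and miR-881-3p lower, with adjusted p-values of 0.0364 and 0.0245, and upper-quartile factors called miR-542-1-3p (adjusted p = 0.0488). Hairpins as a class lay lower in CFA, with a median log2 fold change of -0.92 over 153 features, and of -0.39 over 159 features without controls 1, 2 and 3, whereas the 539 arms had a median of 0.11. Hairpin reads made up 0.938%, 0.414% and 0.598% of counts in controls 1, 2 and 3, and between 0.0833% and 0.343% in the other 17 libraries. Leaving out single libraries ended the count of 0 in 6 of 20 fits, with 7 calls without CFA 8, 7 without control 10, 6 without control 9, 3 without CFA 6, 2 without control 4 and 1 without CFA 5. The hairpin rno-mir-181b-1 was called lower in each of these 6 fits, and the hairpin rno-mir-497 without control 4, 9 or 10 or CFA 6. Most calls in these fits were lower hairpins, except without CFA 8 (5 arms higher and 2 hairpins lower).

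**Figure D2:**
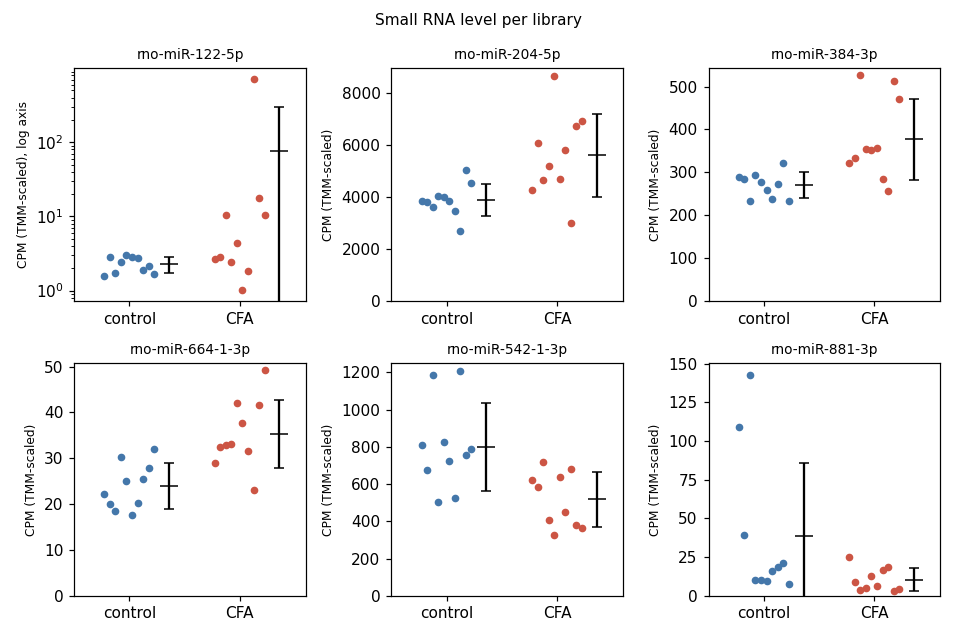
TMM-scaled CPM (vertical axes) of 6 miRNA arms in 10 control (blue) and 10 CFA (red) small RNA libraries, 1 point per library, with the group mean and SD as a black bar. The axis of rno-miR-122-5p is logarithmic and its highest point is CFA 8 at 719 CPM, where the SD bar of the CFA group runs below the axis, and the other axes are linear from 0. None of the 6 passed the edgeR threshold.

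The 8 groups of miRNAs chosen before the data were examined were compared with all other small RNA features by camera. With the preset correlation of 0.01, 5 groups ranked higher in CFA than the other features, and with an estimated correlation 0 did. The 539 arms as a whole had a median log2 fold change of 0.11, against which counts of higher arms must be read. The medians were 0.25 in the let-7 family, 0.17 in the sensory neuron group and 0.149 in the nerve injury group. They were 0.145 in the inflammation-responsive and 0.129 in the Dlk1-Dio3 group. Of 18 arms of the let-7 family, which keeps cells in a differentiated state, 16 had higher values and 2 lower, with a mean log2 fold change of 0.22 (camera adjusted p = 0.000737, and adjusted p = 0.444 with an estimated correlation). Within it, let-7e-3p averaged 29.2 ± 4.25 CPM in controls and 39.2 ± 7.82 CPM in CFA, and let-7e-5p averaged 2564 ± 337 and 3157 ± 682 CPM. The log2 fold changes of let-7e-3p, let-7e-5p and let-7d-3p were 0.42 (0.21 to 0.60), 0.30 (0.12 to 0.46) and 0.27 (0.079 to 0.43). Over all features edgeR called 0 arms of the family and DESeq2 called let-7e-3p (adjusted p = 0.0479), and 1 arm was called by edgeR when adjusted over the list alone. Of 75 arms from the imprinted Dlk1-Dio3 locus, 54 had higher values (camera adjusted p = 0.00360, and adjusted p = 0.619 with an estimated correlation), among them miR-411-3p, miR-758-3p and miR-136-5p with log2 fold changes of 0.44 (0.25 to 0.62), 0.32 (0.17 to 0.50) and 0.28 (0.11 to 0.47).

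Of 39 nerve injury arms, 29 had higher values (camera adjusted p = 0.0127, and adjusted p = 0.444 with an estimated correlation). They included miR-384-3p, the 1 arm called by edgeR when adjusted over the list alone, miR-384-5p at a log2 fold change of 0.36 (0.14 to 0.56), and miR-132-5p, from a gene induced by neuronal activity, at 0.44 (0.27 to 0.62). Of 40 inflammation-responsive arms, 30 had higher values (camera adjusted p = 0.0149, and adjusted p = 0.472 with an estimated correlation), led by let-7e-3p, miR-125a-5p at a log2 fold change of 0.56 (0.16 to 0.76) and miR-132-5p. The level of miR-125a-5p was 8424 CPM in CFA 9 and 8255 CPM in CFA 10, and at most 5735 CPM in controls. Of 17 arms of the sensory neuron group, 15 had higher values (camera adjusted p = 0.0349, and adjusted p = 0.536 with an estimated correlation), led by miR-128-1-3p, miR-9a-1-3p and miR-138-1-3p with log2 fold changes of 0.52, 0.31 (0.13 to 0.51) and 0.24 (0.089 to 0.42). In the last 2 groups and the Dlk1-Dio3 group, edgeR called 0 arms over all features and 0 when adjusted over the list alone, while DESeq2 called 1 inflammation-responsive arm, let-7e-3p, and 0 in the other 2 groups. When arms were compared with arms only, leaving the hairpins out, the let-7 family was the 1 group of 8 that stayed past the threshold with the preset correlation (camera adjusted p = 0.0195), and the other 4 had an adjusted p of 0.590. With an estimated correlation 0 groups passed in that comparison either, with an adjusted p of 0.959 for the let-7 family.

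The remaining groups stand for other cell types that a ganglion sample can hold, and none passed the threshold in the main fit. When single libraries were left out, at least 1 of them passed in some fit. Of 17 blood cell arms, 15 had higher values (camera adjusted p = 0.118), with log2 fold changes of 0.21 (0.0034 to 0.37) for miR-92a-1-3p, 0.30 (0.033 to 0.47) for miR-150-5p and 0.33 (-0.048 to 0.49) for miR-223-3p. Without CFA 3 those of miR-150-5p and miR-223-3p were 0.17 and 0.22. Of 7 muscle arms, 2 had higher and 5 lower values (camera adjusted p = 0.926). Their median and mean log2 fold changes were negative, at -0.11 and -0.06, while the test's direction was up. The muscle arm miR-1-3p averaged 933 ± 976 and 700.2 ± 591 CPM, with control 7 at 3008 CPM. Its log2 fold change was -0.41 (-1.54 to -0.065), but 0.0036 without control 7, -0.23 without control 5 and -0.67 without CFA 3 or CFA 8. That of miR-1b-3p was -0.20 (-0.42 to -0.028), with -0.097 without control 7 and -0.13 without control 5. miR-499-5p had a log2 fold change of 0.36 (0.087 to 0.54). Of 6 epithelial arms, 3 had higher and 3 lower values (camera adjusted p = 0.850), with miR-205-5p at a log2 fold change of -0.29 (-0.69 to -0.066), miR-200c-3p at 0.50 (-0.10 to 0.80) and miR-200a-3p at -0.23 (-0.37 to 0.48). Single libraries moved these values: miR-205-5p was at -0.58 without CFA 9, -0.14 without control 7 and -0.15 without control 2, miR-200c-3p at 0.98 without control 2 and 0.21 without CFA 9, and miR-200a-3p turned to 0.38 without control 2 and 0.086 without control 10. For miR-200a-3p the value also moved to between -0.36 and -0.37 without control 1, 4 or 9, to -0.53 without CFA 6 or 7, and to -0.15, -0.085 and -0.095 without CFA 1, 2 and 3.

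The third comparison asked where DNA methylation differed. The bisulfite files list a mean methylation level and a number of CpG sites per region, and name the regions as differentially methylated. Together they list 2519 regions with a median length of 272 bases, of which 208 have a value in all 20 libraries. Pooling the libraries of each group by CpG number, 1322 regions were higher and 1197 lower in CFA, and 13 of 2519 differed by less than 0.04. The regions thus form a list already selected for a difference between groups, and the counts that follow are not independent evidence of one.

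Of 2434 regions with values in at least 5 libraries per group, 2 passed limma's threshold and both were lower in CFA. Number and direction varied with the setting, with 3 higher and 5 lower without CFA 7, and 6 higher and 5 lower with sample quality weights. At chromosome 10, 91065538 to 91065747 (rn4), the level was 0.781 ± 0.0609 in 6 controls and 0.265 ± 0.177 in 8 CFA libraries, a difference of -0.516 (limma SE 0.0776, adjusted p = 0.00497), over means of 12.7 and 10.8 CpGs. At chromosome 1, 29966126 to 29966335, it was 0.626 ± 0.161 in 10 controls and 0.211 ± 0.134 in 9 CFA libraries, a difference of -0.415 (limma SE 0.0685, adjusted p = 0.00497), over means of 13.4 and 12.4 CpGs. On the logit scale neither region passed, with 0 calls in all. In the main fit, on the levels themselves, 797 regions had an unadjusted limma p under 0.05, where 121.7 would be expected of regions not selected for a difference. Which genes lie at these positions was not analysed here, since no annotation of this build was used.

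**Figure D3:**
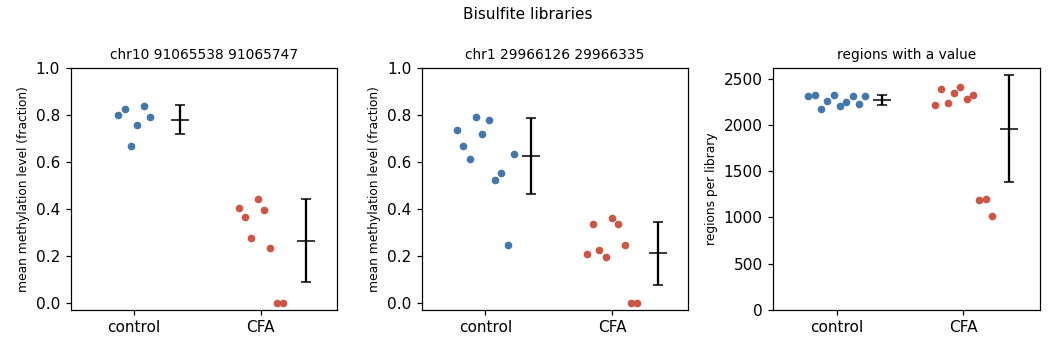
Mean methylation level (fraction, vertical axis) of the 2 regions past limma's threshold in control (blue) and CFA (red) bisulfite libraries, 1 point per library with a value, and the number of regions with a value in each library. Black bars are group means and SD. CFA libraries 8, 9 and 10 are the 3 low points in the right panel, with between 1009 and 1203 regions.

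Among the 208 regions with a value in every library, the largest higher difference was at chromosome 2, 140032257 to 140032717, with 0.271 ± 0.164 in controls and 0.648 ± 0.219 in CFA (limma adjusted p = 0.0566). Regions at chromosome 12, 38611414 to 38611638, chromosome 10, 43746415 to 43746750, chromosome 10, 110093501 to 110094017, and chromosome 14, 7874210 to 7874647, were higher in CFA by 0.288, 0.255, 0.237 and 0.230. The largest lower difference was at chromosome 3, 148384682 to 148384883, with 0.869 ± 0.0537 in controls and 0.560 ± 0.201 in CFA (limma adjusted p = 0.0558). Regions at chromosome 8, 68480229 to 68480375, chromosome 8, 53701254 to 53701437, chromosome 3, 145310203 to 145310702, and chromosome 13, 40660397 to 40660562, had differences of -0.279, -0.269, -0.238 and -0.235. None of these 10 passed limma's threshold over 2434 regions, and when the 208 regions were tested alone 4 of them did, 3 higher and 1 lower. That test called 10 regions in all, 6 higher and 4 lower. Without CFA 8, 9 and 10, the differences of 0.288, 0.255 and 0.237 were 0.160, 0.156 and 0.0569, and those of -0.279 and -0.238 were -0.172 and -0.0629.

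Libraries CFA 8, 9 and 10 had values in 1009 to 1203 regions, against 2175 to 2413 in the other 17. In these 3 libraries between 40.8% and 41.9% of values were exactly 0 or 1, against 3.52% to 8.05% in the others, and the mean number of CpGs per region was 6.52 to 6.85 against 8.79 to 10.3. The 2 regions past the threshold were called without these 3 libraries too. Averaged over the 208 regions, the methylation level was 0.524 ± 0.00973 in controls and 0.533 ± 0.0153 in CFA (SD, n = 10 each), a difference of 0.00889 (p = 0.137, two-sided permutation test). Averaged over all regions of each library, the difference was 0.0170 (p = 0.0269), and 0.00446 without CFA 8, 9 and 10 (p = 0.244).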

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

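All tests that weigh an explanation here were chosen after the result was seen. In each group of 10, the gap from the highest or lowest library to its nearest neighbour was compared with the group's range. Chance singles out about 1 in 20 groups. This picked 1 of 14 groups among the named mRNA genes and 4 of 62 among the named small RNAs.

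rno-miR-122-5p stood at 719 CPM in CFA 8, from 6187 reads, and between 1.01 and 17.7 CPM in the other CFA libraries, with 17.7 CPM in CFA 9 and 10.4 CPM in CFA 10. RNA from liver, where this arm is abundant, may have reached that library. Of 2 further arms abundant in liver, miR-194-1-5p ranked 1 of 20 in CFA 8 at 258 CPM, but the highest other library stood at 254 CPM and the median of the others was 185 CPM. The other arm, miR-192-5p, ranked 8 at 674 CPM, with a high level in every library that would hide a small share. Tissue of another kind taken with the ganglion stays open as well: mRNA library CFA 8 held 1 gene at 5 CPM or more that stayed under 0.5 CPM in the other libraries, and the highest count in another library was also 1. At 1 CPM or more CFA 8 held 7 such genes, the most of any library, and control 10 was next with 5. Blood in the ganglion is a further candidate source, and the mean level of the blood cell arms in CFA 8 was second to CFA 3, with a difference of -0.189 on the log2 scale. None of these 3 was excluded or met what it required, and whether the mRNA and small RNA libraries numbered 8 came from 1 rat is not stated.

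Other libraries that stood apart are given as values. The risen gene with a 3.94-fold difference was at 0.442 CPM in control 5, against 0.920 to 1.81 CPM in the other controls. rno-miR-9a-1-3p was at 428 CPM in control 10, against 549.7 to 706 CPM. rno-miR-205-5p was at 135 CPM in CFA 9, against 34.9 to 58.4 CPM, and rno-let-7e-5p at 4964 CPM in CFA 3, against 2413 to 3285 CPM. Small RNA library control 9 had 1122 features with a read, against 1212 to 1284, and CFA 3 had 1007, against 1122 to 1245. The called region at chromosome 1, 29966126 to 29966335, had a level of 0.246 in control 9, against 0.524 to 0.791 in the other controls.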

How the results depend on the processing

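Values from fits that leave out single libraries or libraries that stood apart, use arms or hairpins only, count hairpins as group members, use a miRNA covariate, or average all regions without CFA 8, 9 and 10 were chosen after the data were seen. The causes of the shifts below were not tested. The 5 mRNA genes were among the calls of every alternative except a mean of at least 1 CPM (4 called) and the block. The gene missing at a mean of at least 1 CPM averaged 0.905 CPM, so that filter removed it before the test. Sample quality weights called 9 genes (7 higher, 2 lower) and surrogate variables 12 (10 higher, 2 lower). Leaving out each library gave 5 to 6 calls. For small RNAs, where edgeR called 0, DESeq2 called 32, upper-quartile factors 4, sample quality weights 4, and arms only without control 1, 2 and 3 and CFA 3, 8, 9 and 10 called 1. Leaving out each library gave 0 to 7. Upper-quartile factors moved the median log2 fold change of the 692 features from 0.02 to -0.14. With no filter the median was -0.20, but over 1318 features, so it is not a shift of the same set. Of the 8 miRNA groups, 5 passed with camera, 0 with an estimated correlation, 0 with fry, 1 with arms only, 0 with arms only and an estimated correlation, 1 with hairpins as members, 3 without controls 1 to 3, and 4 to 6 when each library was left out. Regions past the threshold numbered 2, against 0 on the logit scale, 10 among those complete in every library (6 higher, 4 lower, fewer regions tested), 11 with sample quality weights (6 higher, 5 lower), and 2 to 8 when each library was left out. More than 1.5 times as many were called without control 7 or 8 (4 each), CFA 4 (5), CFA 5 (6) or CFA 7 (8). The mean level over all regions of each library differed by 0.0170 (p = 0.0269). Log2 fold changes changed sign for miR-200a-3p (0.37 with the replicate block, 0.18 without controls 1 to 3, 0.48 with arms only in the smaller set, 0.38 without control 2, 0.086 without control 10), miR-1-3p (0.0036 without control 7), miR-200c-3p (-0.10 with sample quality weights) and miR-223-3p (-0.048 with arms only in the smaller set), none of them called. Of the 31 small RNAs named with a log2 fold change, 21 moved by more than 1.5 times or changed sign with surrogate variables, 20 with upper-quartile factors, 19 with arms only in the smaller set, 14 with no filter, 11 with sample quality weights and 9 when single libraries were left out.

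The labels do not say that replicate numbers mark pairs, and equally numbered libraries did not deviate together throughout. Correlations of the deviations of equally numbered libraries ran from -0.361 to 0.564 in mRNA, -0.416 to 0.605 in small RNA and -0.0389 to 0.132 in bisulfite libraries. Of 10 control libraries, 3, 3 and 1 matched their own number best. With the replicate block, 2 mRNA genes, 12 small RNAs (among them miR-204-5p, miR-542-1-3p and miR-128-1-3p, adjusted p = 0.0353 each), 5 miRNA groups and 1 region were called, and the mean methylation difference of 0.00889 had p = 0.152. Not run, for want of gene names and annotation, were the alternatives for the mRNA gene groups, the AP-1 motif and genes near regions. The 95% interval lay within 2-fold for 69.9% of small RNA features and 95.4% of mRNA genes. A methylation shift of 0.2 was recovered in 8 of 60 simulated regions, and the read depth of the regions is unknown.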

Other observations

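The tests of explanations and the relations between libraries in this part were chosen after the results were seen, except the counts over other splits of the libraries. The mRNA libraries spread mainly along a component for which no difference between the groups was detected, and which held 40.5% of the variance. CFA 3, control 10 and CFA 8 lay at its low end, at -107, -60.7 and -34.7. Over the 20 equally numbered libraries, 16 relations of the first 2 components with the 8 miRNA groups were computed. The first component followed the blood cell arms (r = -0.745, permutation p = 0.000230, adjusted p = 0.00368, rho = -0.609, permutation p = 0.00554, adjusted p = 0.0400) and the inflammation-responsive arms (r = -0.702, permutation p = 0.000820, adjusted p = 0.00656, rho = -0.523, permutation p = 0.0200, adjusted p = 0.0550). It followed the Dlk1-Dio3 arms (r = 0.618, permutation p = 0.00403, adjusted p = 0.0156, rho = 0.57, permutation p = 0.010, adjusted p = 0.0400) and the sensory neuron arms (r = 0.589, permutation p = 0.00488, adjusted p = 0.0156, rho = 0.573, permutation p = 0.00987, adjusted p = 0.0400). Without the 2 libraries farthest from the median of each group of arms, r was -0.522, -0.662, 0.356 and 0.564 in that order, so the Dlk1-Dio3 relation rests largely on CFA 8 and CFA 3. Within controls r was -0.639, -0.387, 0.105 and 0.257, and within CFA libraries -0.818, -0.923, 0.814 and 0.756. The second component followed the muscle arms (r = 0.611, permutation p = 0.00370, adjusted p = 0.0156, rho = 0.726, permutation p = 0.000480, adjusted p = 0.00768, and r = 0.523 without control 7 and CFA 8), with r = 0.626 within controls and 0.722 within CFA libraries.

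Explanations were weighed for that main spread. CFA injection was argued against by a permutation p of 0.973 for the difference between groups, with r = -0.00911 between component and group (95% interval from -0.45 to 0.435). The bound on r behind that verdict was set after the results were seen. A relation as large as the limits of that interval is not excluded. Library size stays open, since r = 0.203 with the log2 total count had a 95% interval from -0.263 to 0.592. A candidate explanation is a varying share of sensory neurons in the tissue taken, for which the relation with the sensory neuron arms (r = 0.589) had 1 sign in both groups and was weaker within controls. Blood in the tissue is another, with r = -0.745 for the blood cell arms. The 2 were not separated, and both assume that equal numbers in the mRNA and small RNA sets mark 1 rat, which the labels do not state.

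Hairpin features lay lower in CFA, with a difference of -0.753 in their mean log2 CPM (permutation p = 0.0137). Controls 1, 2 and 3, with the highest shares of hairpin reads, may contribute: without them the difference was -0.427 (permutation p = 0.118) and the median log2 fold change of hairpins went from -0.92 to -0.39. Leaving out the controls highest in hairpin reads shrinks such a difference whatever its cause, and fewer libraries raise p. These values therefore cannot tell whether the 3 controls are the whole cause. In the 17 libraries left, 26 hairpins were still lower and 0 higher at an unadjusted p under 0.05, so a remainder is not excluded. CFA injection stays open, since the share of hairpin reads differed by -0.151 percentage points over 20 libraries (permutation p = 0.0851) and by -0.010 without controls 1 to 3 (permutation p = 0.779). Why the 3 controls differ was not tested.

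Over 100 splits of the 20 mRNA libraries into 10 and 10, the real one included, 1 split gave 5 or more genes, the real one, and the highest of the others gave 0. The smallest share that 100 splits can give is 1 in 100, so chance is made unlikely for that count but is not excluded. These splits took no account of possible pairs, and the replicate block called 2 genes. Other splits reached 4164 genes at an unadjusted p under 0.05, against 314 in the real split, which points to a structure of the libraries other than the groups. For small RNAs the real split gave 0 calls, which any split equals (100 of 100, with 9 as the highest of the others), so this count says nothing about chance. For methylation, 3 of 100 splits gave 2 regions or more, with 2 as the highest of the others. Since the regions were selected on these same libraries, that share does not exclude chance.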
